A study of Arabidopsis thaliana with 12 samples.

How the data were processed

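RNA from shoot apices of Arabidopsis thaliana was measured on 12 one-colour oligonucleotide arrays, 1 for each of 4 genotypes on each of 3 days. Per the labels, plants grew for 30 days at 21 °C in short days of 9 h light and 15 h dark and then moved to long days of 16 h light and 8 h dark, and apices were taken on day 0, day 2 and day 4 after the move. The genotypes combine 2 alleles each of FRIGIDA (FRI) and FLOWERING LOCUS C (FLC). friCol-FLC is the Col-0 wild type, friCol-flc3 carries a deletion of FLC, FRISf2-FLC carries the active FRI allele of accession Sf-2 with an intact FLC, and FRISf2-flc3 carries that FRI allele with the deletion. Groups were taken from the sample titles. Each group of genotype and day holds 1 array, so no group has a replicate, and the labels say neither how many plants were pooled nor at which hour apices were taken.

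The deposited table holds 1 log2 value per probe set and array, from 2.12 to 13.18. The unit was read from the deposited values, since no header or label names it: as natural or decimal logarithms the top values would lie beyond what an array scanner can record. The software and the normalization used by the authors are not given in the sources used here. The array medians of the deposited log2 values lay within 0.058 of each other, so the values were used as deposited. The number of arrays limits the precision.

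Of 8297 probe sets, 50 were controls and were left out of the tests. Of the other 8247, the platform annotation gave 1 gene for 3794 probe sets, several for 70 and none for 4383; the 3794 stand for 3602 different genes, and 3784 of them were found in the RefSeq gene table of assembly TAIR10.1. No gene was named from a probe set with several. In the annotation no probe set was paired with FLC or FRI alone, nor with SOC1, FT, LFY, AP1, FUL, SMZ or SNZ. These genes are therefore not analysed by name, though probe sets without a gene name may measure some of them. No genome coordinates are given, because the array design and the gene table name no common build. Probe sets entered the tests when their mean over the 12 arrays lay above the 25th percentile (3.56), which left 6185, of which 2736 had 1 gene.

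The comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend) on all 12 arrays, two-sided, with Benjamini-Hochberg adjustment over the 6185 probe sets and a threshold of 0.05. The model was additive in genotype and day and left 6 residual degrees of freedom, to which the prior added 5.93. The spread is therefore what an additive model leaves, which mixes real differences in the day response between genotypes with the noise of single arrays; each standard error (SE) below is of that kind. A second model let FRISf2-FLC have its own day terms and left 4 residual degrees of freedom. The 9 comparisons were FRISf2-FLC against the mean of the other 3 genotypes, the effect of FLC with and without active FRI, the effect of the Sf-2 FRI allele with and without FLC, the interaction of FRI and FLC, day 2 and day 4 against day 0, and the day 4 response of FRISf2-FLC against the mean response of the other 3 genotypes.

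The rule for named genes, the gene lists, the 9 comparisons and their thresholds were chosen before the data were examined. Named genes are, per comparison, the 10 largest rises and the 10 largest falls among eligible probe sets. An eligible probe set had an adjusted p under 0.05 and 1 gene name. Its sign was the same on all 3 days (genotype comparisons) or in all 4 genotypes (day comparisons). Every called member of 16 gene lists was named too. The rule also held FRI, FLC and the flowering genes listed above, but the annotation paired no probe set with any of them alone. Further parts of the rule, for lists that pass the set test and for comparisons without a call, did not apply. Probe sets without a gene name that are cited by their identifier, and genes cited as examples of the broader groups, were chosen after their values were seen. The 16 lists hold 291 genes, but only 18 had a named probe set (26 probe sets, 23 tested). Counts adjusted within each list alone use the 1 to 4 tested probe sets of that list. They have no adjustment across lists, so they lie close to unadjusted counts. No list had more than 2 genes, so the set test planned for them was not run. In its place 13 groups of genes were put together from the symbols in the annotation, after the annotation but before any comparison was computed, by symbol alone (POR and PEL1 were misplaced this way, as found afterwards), and tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation.

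The share of called probe sets near FRI was tested with Fisher's exact test, two-sided, between the loci AT4G00005 to AT4G02999 and all others with 1 locus name. Alternatives fixed beforehand were quantile normalization, median centring, no filter, a filter at the 50th percentile, no trend, a robust trend, day as a number with a slope in each genotype, only the 6 arrays of the 2 genotypes compared, only the 3 genotypes other than FRISf2-FLC for the day comparisons, 2 other lengths of the segment, and leaving out each of the 12 arrays. Array weights, the size of the response in each genotype, the segment counts at an unadjusted p, a scan of locus bins, a smaller flower group and splits balanced over days or genotypes were added after the data were seen.

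All 9 fits were tested on simulated arrays with the residual spread of the real ones, 6185 probe sets and 200 changed ones. For day 4 against day 0, 97.0% of changes of 1 on the log2 scale and 76.1% of changes of 0.5 were recovered, and 3.19% of the calls were false. For FRISf2-FLC against the other genotypes the shares were 98.5% and 82.1%, with 2.09% false. For the day 4 response of FRISf2-FLC, 93.9% of changes of 2, 43.3% of changes of 1 and 0% of changes of 0.5 were recovered, and 7.14% of the calls were false. The false share was above the nominal 5% for day 2 too (6.19%) and for the FLC effects without (5.95%) and with active FRI (5.41%), and was 3.37%, 3.45% and 4.2% for the FRI effects with and without FLC and the interaction. Each share rests on 1 simulated set of arrays, for example 12 false of 194 calls for day 2 and 10 of 185 for the FLC effect with active FRI. Small differences from 5% or between comparisons are therefore not settled. These simulated arrays had independent probe sets and equal quality, which the real arrays need not share. Figures were drawn with matplotlib 3.10.9.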

Results

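The data are 12 arrays of shoot apex RNA, 1 for each of 4 genotypes at 0, 2 and 4 days after plants moved from short days to long days. FRI and FLC are regulators of flowering time: an active FRI raises FLC, a MADS-box repressor of flowering, and Col-0 carries an inactive FRI. Neither gene had a probe set of its own in the annotation, so the genotype labels were not checked on the targeted genes. There were no replicates within a genotype and day; each genotype comparison rests on 3 arrays per genotype, 1 per day, and each day comparison on 4 arrays per day, 1 per genotype. The first principal component held 42.0% of the variance and followed the day. The FRISf2-flc3 day 2 array differed from the other 11 in its hybridisation controls, with BioB at 9.53 against 7.14 to 7.79 (log2), and in its residual spread, 0.166 against 0.0969 to 0.132.

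The genotype with active FRI and intact FLC, FRISf2-FLC, was compared with the mean of the other 3 genotypes. One probe set without a gene name, 17501_s_at, stood furthest apart. The annotation does not give its gene, so whether it measures FLC itself, which differs between these genotypes by design, is not known. It measured 9.29 ± 0.0534 (SD over the 3 days, log2) in FRISf2-FLC, 6.66 ± 0.685 in friCol-FLC, 5.90 ± 0.201 in FRISf2-flc3 and 5.50 ± 0.331 in friCol-flc3, a fitted difference of 3.28 ± 0.153 (SE, log2), or 9.69-fold, with a limma adjusted p of 4.44e-07. Among named genes, AT1G76960 was higher in FRISf2-FLC by 1.02 ± 0.197 and the jacalin-related lectin gene JAL34 by 0.98 ± 0.155. AT1G54010, a GDSL lipase-like gene, was higher by 0.82 ± 0.146, AT1G52100, another jacalin-type lectin gene, by 0.76 ± 0.0963, and the beta-glucosidase gene BGLU47 by 0.51 ± 0.0758. AT4G02850, AT2G30840, AT4G16190 and AT2G31790 were higher by 0.61, 0.48, 0.41 and 0.38. The AT4G16190 value is for 1 probe set, and another probe set of that gene was not called. AT4G01590 and AT3G16280 were lower, with differences of -1.26 ± 0.161 and -0.36 ± 0.073.

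In all, 47 of 6185 probe sets passed the threshold, 27 higher and 20 lower in FRISf2-FLC, and all 47 had the same sign on each of the 3 days. The lower ones include 15515_r_at and 12336_at, which like AT4G01590 were also low in FRISf2-flc3. Their means were 7.24 and 4.59 there and 7.455 and 4.485 in FRISf2-FLC. A beta-glucosidase group of 8 probe sets held 1 put in by its symbol in error (PEL1, a pelota gene). Of the 8, 1 passed, BGLU47, and BGLU33 measured 0.55 ± 0.146 without passing (limma adjusted p = 0.128). The group tested higher at the preset correlation only (camera adjusted p = 0.014, and 0.00411 without PEL1). With an estimated correlation the camera adjusted p was 0.209. In a group put together as flower, anther and pollen genes, 4 of 10 probe sets belong to YAB3, PHV and STOMAGEN, genes of organ polarity and stomata; no probe set passed in limma, and the median was -0.12 (camera adjusted p = 0.0165; adjusted p = 0.209 with an estimated correlation). Without those 4 probe sets, a setting added after the data were seen, the group did not pass (camera adjusted p = 0.0606; adjusted p = 0.47 with an estimated correlation). Of the 23 probe sets in the lists fixed beforehand, 0 passed over all probe sets. When adjusted within each list alone, with no adjustment across lists, 2 higher and 3 lower passed. No other group passed the set test. The count was 9 with day as a number, 30 with quantile normalization and 155 with array weights (a setting added after the data were seen), and leaving out 1 array gave 5 (FRISf2-FLC day 2), 20 (FRISf2-FLC day 4), 21 (friCol-FLC day 4), 22 (FRISf2-flc3 day 4), 27 (FRISf2-flc3 day 0), 30 (friCol-FLC day 0) or 31 (friCol-flc3 day 4). AT1G52100 kept its call in 19 of 20 alternative settings, AT4G01590 in 18 of 19, JAL34 and BGLU47 in 16 of 19, and AT2G30840 in 17 of 20, while of 20 AT1G54010 kept its call in 12, AT1G76960 and AT4G02850 in 8, AT4G16190 and AT2G31790 in 5 and AT3G16280 in 2.

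**Figure D1:**
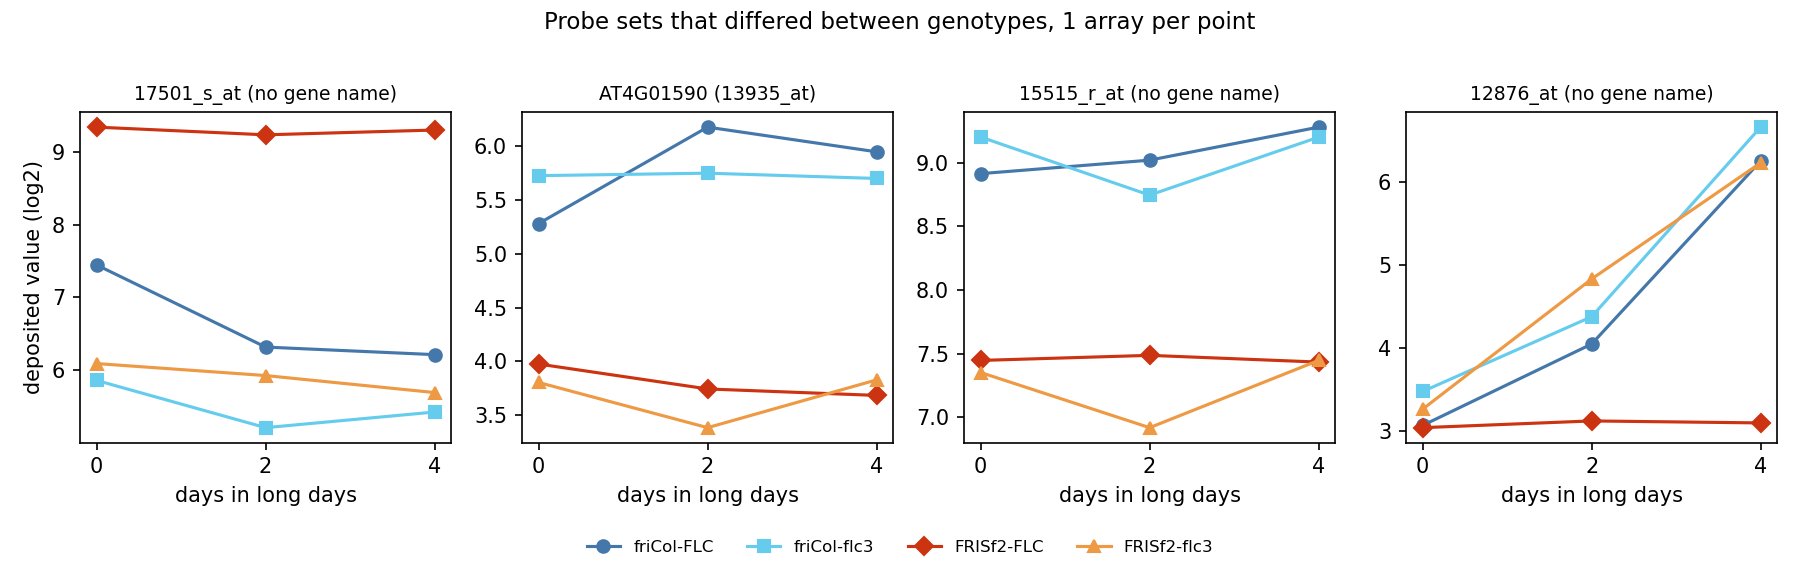
Deposited log2 values (vertical axes, 1 scale per panel) against days in long days (horizontal axes) for 4 probe sets, with 1 array per point and 1 line per genotype. 17501_s_at lies at 9.24 to 9.34 in FRISf2-FLC, AT4G01590 and 15515_r_at are lower in both genotypes with the Sf-2 FRI allele, and 12876_at reaches 6.23 to 6.66 on day 4 in every genotype except FRISf2-FLC, where it is 3.1.

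The effect of FLC in plants with active FRI was measured as FRISf2-FLC minus FRISf2-flc3. AT4G16190, which encodes a papain-like cysteine protease, was the only called gene with a name, higher with FLC by 0.61 ± 0.102 (adjusted p = 0.0447). This call rests on 1 probe set, and another probe set of the gene did not pass. On days 0, 2 and 4 that other probe set measured 9.00, 8.07 and 7.66 in FRISf2-FLC. In FRISf2-flc3 it measured 8.62, 7.50 and 7.12, so it was higher with FLC on each day, but without a call. The probe set 17501_s_at, which may measure FLC itself, was higher by 3.39 ± 0.188, or 10.51-fold, and 16586_s_at by 0.99 ± 0.0925. In contrast, 16341_at and 16422_at differed by -1.31 ± 0.153 and -0.75 ± 0.10. For 16586_s_at and 16341_at only FRISf2-flc3 stood apart, with means of 4.55 and 5.60. In friCol-flc3, which also lacks FLC, they measured 5.67 and 4.31, near the 5.68 and 4.26 of friCol-FLC. Their differences therefore did not follow the FLC deletion in both FRI backgrounds. In total 9 probe sets passed, 4 higher and 5 lower. Of the 23 list probe sets 0 passed over all probe sets, and 2 higher and 2 lower passed when adjusted within each list alone. No group passed the set test. The count was 15 with the filter at the 50th percentile, 14 with a robust trend, 30 with only the 6 arrays of these genotypes and 96 with array weights, and leaving out 1 array gave 2 (FRISf2-flc3 day 0), 3 (FRISf2-flc3 day 4), 4 (FRISf2-flc3 day 2, FRISf2-FLC day 2 or friCol-FLC day 4), 19 (friCol-FLC day 2), 24 (friCol-flc3 day 4) or 27 (FRISf2-FLC day 0). AT4G16190 kept its call in 8 of 21 alternative settings and 16422_at in 15 of 21. 16341_at kept its call in 19 of 20, and 17501_s_at and 16586_s_at in 21 of 21.

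The effect of FLC in plants with the inactive FRI of Col-0 was friCol-FLC minus friCol-flc3. CCL, a gene whose name stands for CCR-like, was lower with FLC, with a difference of -0.91 ± 0.113 (adjusted p = 0.0222), and was the only probe set to pass. Photosynthesis and chlorophyll genes tested lower with FLC at the preset correlation only. None of 25 probe sets passed alone in limma, and their median was -0.14. The camera adjusted p was 3.33e-09, and 0.113 with an estimated correlation. The group holds 1 probe set of POR, a tubulin folding gene put in by its symbol in error. Without it the camera adjusted p was 1.18e-09 here, 5.26e-05 for the FRI effect with FLC, 9.99e-05 for the interaction and 0.0299 for day 2. With an estimated correlation these camera adjusted p-values were 0.125, 0.244, 0.271 and 0.51, so none passed. PORB, an enzyme of chlorophyll synthesis, measured -0.26 ± 0.0965 and HEME2 -0.31 ± 0.089. In limma 153 probe sets had an unadjusted p under 0.05, where chance gives 309. Of the 23 list probe sets, 0 higher and 3 lower passed when adjusted within each list alone. CCL kept its call in 11 of 21 alternative settings. No probe set passed in limma with day as a number, with only the 6 arrays of these genotypes, or without any 1 of friCol-FLC day 0, friCol-FLC day 2, the 3 friCol-flc3 arrays, FRISf2-FLC day 0 and FRISf2-flc3 day 0, each with a count of 0, while 2 passed without friCol-FLC day 4, with CCL not among them, or without FRISf2-FLC day 2, with CCL as 1 of them.

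The effect of the Sf-2 FRI allele with FLC present was FRISf2-FLC minus friCol-FLC. AT1G52100 was higher by 0.77 ± 0.118 and BGLU47 by 0.61 ± 0.0928, while AT4G01590 was lower, with a difference of -2.0 ± 0.198. 17501_s_at was higher by 2.64 ± 0.188 and 17953_at by 0.91 ± 0.098, and 15515_r_at and 12336_at differed by -1.62 ± 0.128 and -0.93 ± 0.103. In total 11 probe sets passed, 5 higher and 6 lower. Photosynthesis genes tested higher at the preset correlation only, with a median of 0.13 (camera adjusted p = 0.00014, and 0.243 with an estimated correlation). The same held for the beta-glucosidase group (camera adjusted p = 0.0138, and 0.00213 without PEL1). Its camera adjusted p was 0.243 with an estimated correlation. The flower, anther and pollen group, which holds YAB3, PHV and STOMAGEN too, had a median of -0.11 (camera adjusted p = 0.0216, and 0.265 with an estimated correlation). Without those 3 genes its camera adjusted p was 0.0324 (adjusted p = 0.44 with an estimated correlation). The photosynthesis result shares the friCol-FLC arrays with that of the FLC effect without active FRI. Of the list probe sets, 0 passed over all probe sets, and 3 higher and 1 lower passed when adjusted within each list alone. With day as a number 5 probe sets passed and with array weights 44, and leaving out 1 array gave 6 (friCol-FLC day 0 or day 2), 7 (FRISf2-FLC day 2) or 18 (FRISf2-FLC day 0). AT1G52100 kept its call in 15 of 21 alternative settings and BGLU47 in 14 of 20.

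The effect of the Sf-2 FRI allele without FLC was FRISf2-flc3 minus friCol-flc3. AT4G01590 was again lower with the Sf-2 allele, by a difference of -2.05 ± 0.198 (adjusted p = 0.000531), and was the only named gene among 5 called probe sets. 15515_r_at differed by -1.81 ± 0.128, 16586_s_at by -1.12 ± 0.0925 and 16341_at by 1.29 ± 0.153. For 16586_s_at and 16341_at only FRISf2-flc3 stood apart. FRISf2-FLC, with the same FRI allele, had means of 5.55 and 4.29, near the 5.67 and 4.31 of friCol-flc3. The effects of the FRI allele with and without FLC share no arrays, though both use the same residual spread. Their lists of lower probe sets held 6 and 4, and 3 were in both (12336_at, AT4G01590 and 15515_r_at), against 0.00388 for independent lists (Fisher's exact test, two-sided, p = 2.03e-09). Of the list probe sets 0 passed over all probe sets, and 0 higher and 1 lower passed when adjusted within each list alone. No group passed the set test. The count was 2 with the filter at the 50th percentile, 3 with day as a number, 11 with only the 6 arrays of these genotypes and 18 with array weights.

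By its locus name FRI lies near the top of chromosome 4, and the Sf-2 allele came in by introgression. Of 81 tested probe sets with loci AT4G00005 to AT4G02999, 1 (AT4G01590) was called for the FRI effect without FLC, against 0 of 2653 elsewhere (Fisher's exact test, two-sided, p = 0.0296), and 1 against 2 for the FRI effect with FLC (exact p = 0.0863). These p-values rest on AT4G01590 alone. By probe sets with an unadjusted p under 0.05, a count added after the data were seen, the segment held 17 of 81 for the FRI effect without FLC, against 179 of 2653 elsewhere (exact p = 3.73e-05), and 10 against 140 for the FRI effect with FLC (exact p = 0.0119). For the FLC effects, which compare plants with the same FRI allele, it held 7 against 279 with active FRI (exact p = 0.714) and 2 against 47 without (exact p = 0.656). With a segment ending at AT4G00999 the p of 0.0296 became 1, since AT4G01590 then lies outside. By unadjusted p, the FRI effect with FLC gave an exact p of 0.197 with that end (2 of 15) and 0.0869 with an end at AT4G05999 (10 of 109), so it was under 0.05 only with the end at AT4G02999, and the FRI effect without FLC gave 0.0187 (4 of 15) and 0.000814 (18 of 109).

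The interaction of FRI and FLC asks whether FLC changes expression by a different amount when FRI is active. 17501_s_at had an FLC effect larger by 2.23 ± 0.266 with active FRI (adjusted p = 0.0148), and 16586_s_at one larger by 0.98 ± 0.131 (adjusted p = 0.0228). No named gene passed. Whether 17501_s_at measures FLC itself is not known. If it does, its difference is that of the FLC transcript and not of a gene that responds to FLC. 16586_s_at measured 4.55 ± 0.144 (SD over days) in FRISf2-flc3 and 5.55 to 5.68 as the means of the other genotypes. Photosynthesis and chlorophyll genes had a median of 0.16 (camera adjusted p = 0.000158, and 0.249 with an estimated correlation), with HEME2 at 0.58 ± 0.126. This result, that of the FLC effect without active FRI and that of the FRI effect with FLC all use the friCol-FLC arrays. They are therefore not separate observations. Without those arrays, the group median was 0.02 for the FLC effect with active FRI (camera adjusted p = 0.325). It was -0.08 for the FRI effect without FLC (camera adjusted p = 0.229). Of the list probe sets 0 passed over all probe sets, and 5 above and 0 below passed when adjusted within each list alone. Both calls ended, with a count of 0, without any 1 of friCol-flc3 day 0, friCol-flc3 day 4, FRISf2-FLC day 2, FRISf2-flc3 day 0 and FRISf2-flc3 day 4. The count was 1 without friCol-FLC day 0 or friCol-flc3 day 2, 4 without friCol-FLC day 2 or day 4, and 9 without FRISf2-FLC day 0 or with array weights. With day as a number 2 probe sets passed, of which 1 was among these calls. 17501_s_at kept its call in 15 of 20 alternative settings and 16586_s_at in 12 of 20.

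After 2 long days the thionin gene THI2.1 had risen by 1.64 ± 0.306 and 1.48 ± 0.315 on 2 probe sets, AT4G33560 by 1.80 ± 0.195, AT1G04660 by 1.5 ± 0.125, and the lectin gene JAL23 by 1.29 ± 0.266. AT1G54020, AT2G20870, AT1G60590 and AT1G03746 rose by 1.44, 1.3, 1.13 and 1.04. The methionine sulfoxide reductase gene MSRB5 changed by -2.14 ± 0.149, AT2G25450 by -1.72 ± 0.124, CCL by -1.66 ± 0.0977, and GIGANTEA (GI), a gene of the circadian clock and the photoperiod pathway, by -1.21 ± 0.0974. The hour of sampling is not given in the labels, and the light period was 9 h up to day 0 and 16 h after it. No array is of plants kept in short days past day 0. Long days therefore cannot be told apart from plant age or the occasion of harvest. AT4G33960, the glutathione transferase gene GSTF3, AT4G16190, AT2G05540 and AT1G13930 changed by -1.26, -1.20, -1.19, -1.17 and -1.12. The AT4G16190 value here is from the probe set of that gene that was not called between genotypes. The probe set called there changed by -1.08 ± 0.088. In total 661 probe sets passed, 297 up and 364 down, 653 of them with the same sign in all 4 genotypes. In the lists fixed beforehand the Aurora kinase gene AUR2 rose by 0.43 ± 0.0834 and DFR, an enzyme of anthocyanin synthesis, by 0.79 ± 0.18. In contrast, 3 probe sets of GI and 2 of the dehydrin gene COR47 fell. These are 2 up and 5 down of 23 over all probe sets, and 2 up and 6 down adjusted within each list alone. Photosynthesis and chlorophyll genes tested up at the preset correlation only, with 3 up, 1 down and 21 not called of 25. The camera adjusted p was 0.0256, and 0.479 with an estimated correlation. SBPASE measured 0.49 ± 0.0851 and PORB -0.58 ± 0.0836. No other group passed the set test. The photosynthesis group's adjusted p was 0.0685 without the FRISf2-flc3 day 2 array. The count of called probe sets was 422, 428 and 432 without the day 0 arrays of friCol-flc3, friCol-FLC and FRISf2-flc3.

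After 4 long days the changes were more numerous, again without plants kept in short days for comparison. THI2.1 rose by 3.14 ± 0.306, or 8.79-fold, and by 2.96 ± 0.315 on its second probe set, while a further probe set of the gene measured 0.28 ± 0.118 without passing. AT1G54020, a GDSL lipase-like gene, rose by 2.01 ± 0.288, AT4G33560 by 1.81 ± 0.195, AT2G20870 by 1.47 ± 0.246, AT1G04660 by 1.3 ± 0.125 and JAL23 by 1.25 ± 0.266. AT4G15430 and AT4G28780 rose by 1.14 and 1.13. AT2G25450, an oxygenase of glucosinolate synthesis, changed by -3.70 ± 0.124, a 13.03-fold fall, and MSRB5 by -3.49 ± 0.149. CCL changed by -2.15 ± 0.0977, the extensin-like gene AT2G43150 by -2.04 ± 0.103, GSTF3 by -1.91 ± 0.129, AT2G05540 by -1.74 ± 0.231, GI by -1.64 ± 0.0974, and the peroxidase genes AT2G38380 and AT4G37520 by -1.66 ± 0.26 and -1.57 ± 0.153. Probe sets with the suffixes _f_at, _s_at and _i_at, among them those of GSTF3, CCL and MSRB5, can also bind related transcripts. In total 1130 probe sets passed, 543 up and 587 down, and 1107 had the same sign in all 4 genotypes; 467 had passed on day 2 too, 464 of them with the same sign, though both comparisons share the day 0 arrays.

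**Figure D2:**
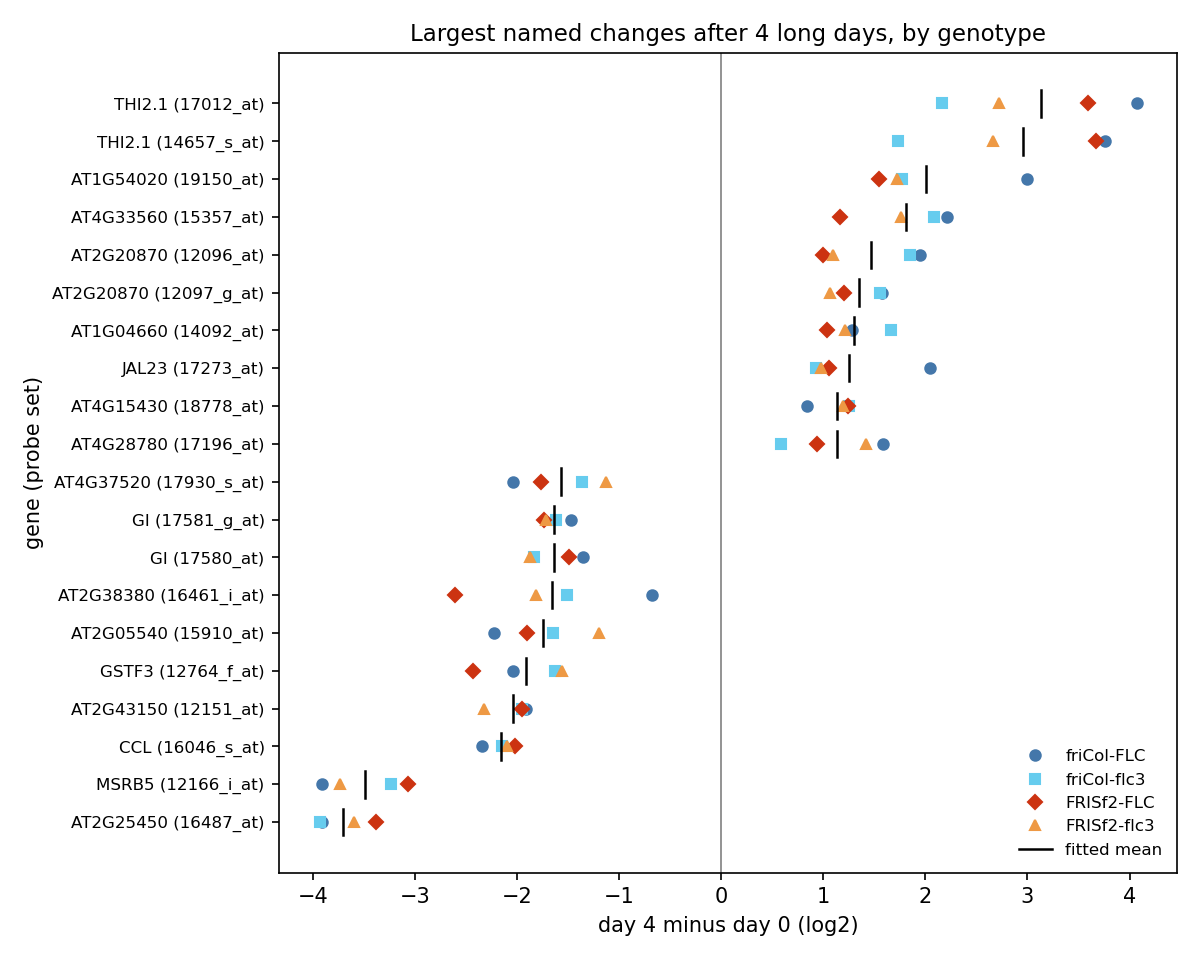
Day 4 minus day 0 (horizontal axis, log2) for the named probe sets with the 10 largest rises and the 10 largest falls (vertical axis), with 1 point per genotype and a bar at the fitted mean. AT2G25450 and THI2.1 lie at the ends, at -3.70 and 3.14, and all 4 genotypes lie on the same side of 0 for each probe set.

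Of the 23 probe sets in the lists fixed beforehand, 3 rose and 7 fell on day 4 over all probe sets. When adjusted within each list alone, 5 rose and 11 fell. In the photoperiod and clock list all 3 tested probe sets belong to GI and fell. In the cold, drought and heat list all 4 probe sets fell, COR47 by -1.10 ± 0.113 and -1.08 ± 0.128 and KIN2 by -0.70 ± 0.176 on each of 2 probe sets. In the shoot meristem and organ boundary list 2 of 3 passed: YAB3, which helps set organ polarity, rose by 0.29 ± 0.0746 on 1 of 2 probe sets and PHV, a leaf polarity and meristem factor, by 0.29 ± 0.0892. In the cell cycle list AUR2 rose by 0.50 ± 0.0834 and MCM7 measured -0.09 ± 0.194. The floral organ identity genes UFO (0.25 ± 0.12) and SPT (-0.03 ± 0.109), the FLC regulator LD (-0.17 ± 0.114), RCA (-0.33 ± 0.106) and LHCB4.1 (-0.21 ± 0.0693) of photosynthesis, WRKY53 (0.12 ± 0.125) and ZAT10 (-1.02 ± 0.349) of the defence list, DFR (0.36 ± 0.18) of anthocyanin synthesis, SLY1 (0.20 ± 0.0755) of gibberellin signalling and APL3 (-0.14 ± 0.106) of starch synthesis did not pass. AGL19, in the list of flowering integrators, had a mean of 3.13 and lay under the filter, and the lists of other floral repressors, neighbours of FLC, vascular tissue and epidermis had no named probe set.

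Among the broader groups, cold, dehydration and late embryogenesis genes tested down on day 4 at the preset correlation only. Of 22 probe sets, 3 rose, 8 fell and 11 were not called, with a median of -0.38. The camera adjusted p was 0.00526, and 0.105 with an estimated correlation. The osmotin gene OSM34 fell by a difference of -1.46 ± 0.207 and LTI30 by -0.50 ± 0.147, while EEL, a bZIP factor, rose by 0.86 ± 0.13. No other group passed the set test. Photosynthesis genes went both ways (3 up, 4 down of 25), with LHCB4.3 at 0.84 ± 0.124 and PORB at -0.64 ± 0.0836, as did cell wall genes (4 up, 1 down of 28), with EXPA20 at 0.62 ± 0.0819 and EXPA8 at -0.97 ± 0.168. In the defence group 4 rose and 3 fell of 23, with ATLP-1 at 0.73 ± 0.0873 and THI2.2 at -1.27 ± 0.201, opposite to THI2.1. The group of tubulins, actins and myosins, which also holds the LIM protein genes WLIM1, WLIM2a and WLIM2b and SPR1, had 1 up and 4 down of 11, with ACT11 at 0.66 ± 0.122 and TUB5 at -0.45 ± 0.083; the other 3 falls were the LIM genes. UDP-glycosyltransferases had 2 up and 5 down of 17, with UGT74B1, an enzyme of glucosinolate synthesis, at -0.84 ± 0.107. Cell division genes had 2 up and 0 down of 13, the flower, anther and pollen group 2 up and 0 down of 10 (the YAB3 and PHV probe sets given above), the beta-glucosidase group 0 up and 2 down of 8, auxin genes 1 up and 1 down of 14, and autophagy and vacuole genes 0 up and 1 down of 16. The photosynthesis and autophagy groups had a median above 0 and a set test pointing down. No probe set passed in limma among 10 of serine carboxypeptidase-like and 5 of AGAMOUS-LIKE genes.

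The day 4 response of FRISf2-FLC was set against the mean response of the other 3 genotypes. The probe set 12876_at, which has no gene name, was the only one to pass: it rose from 3.07, 3.48 and 3.27 to 6.25, 6.66 and 6.23 in friCol-FLC, friCol-flc3 and FRISf2-flc3 and went from 3.04 to 3.1 in FRISf2-FLC, a difference of -3.05 ± 0.324 in deposited values (adjusted p = 0.013). Its FRISf2-FLC values and its day 0 values all lay under the filter value of 3.56, and no detection calls were used here, so the size of the difference is not settled. No gene with a name passed, and 119 probe sets had an unadjusted p under 0.05 in limma, where chance gives 309. Of the list probe sets 0 passed over all probe sets, and 2 above and 0 below passed when adjusted within each list alone. No group passed the set test. The 12876_at call was absent with the filter at the 50th percentile and without the friCol-flc3 day 4 array, while 2 probe sets passed with no trend or a robust trend and 16 with array weights.

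The size of the response in each genotype was measured, by a method chosen after the data were seen, on probe sets called from the other 3 genotypes alone. In FRISf2-FLC 468 such probe sets had a mean signed change of 0.50 on day 2, against 0.77 in the others, a ratio of 0.654, and 769 had 0.63 on day 4, against 0.79, a ratio of 0.80. The same ratios were 0.939 and 0.995 in friCol-FLC, 0.985 and 0.941 in friCol-flc3, and 0.842 and 0.932 in FRISf2-flc3. The changes in FRISf2-FLC had the direction of the other genotypes for 95.9% of these probe sets on day 2 and 95.4% on day 4. With 1 array per genotype and day these ratios have no replicate error. The probe sets were chosen for passing in the genotypes that form the divisor, which tends to enlarge that divisor. A ratio under 1 can therefore arise from the choice alone, and every ratio was under 1. For the other genotypes the divisor includes FRISf2-FLC, which raises their ratios, so these are not a clean baseline either.

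**Figure D3:**
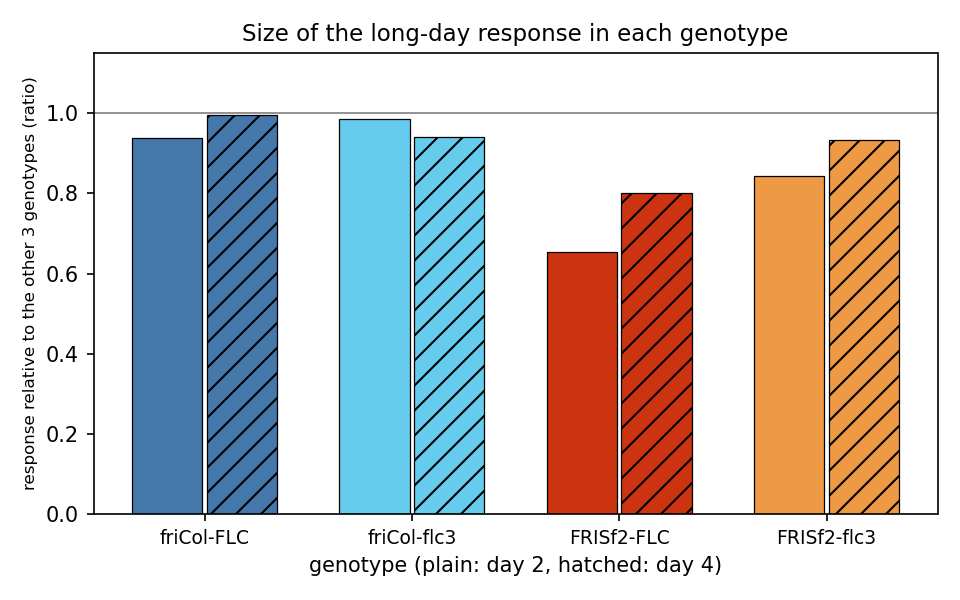
Mean signed change in each genotype divided by that of the other 3 genotypes (vertical axis, ratio, from 0), for each genotype (horizontal axis), on day 2 (plain bars) and day 4 (hatched bars), without error bars because each value rests on single arrays. FRISf2-FLC has the lowest ratio on both days, 0.654 and 0.80. Choosing the probe sets from the genotypes in the divisor tends to lower every ratio, so 1 is not a clean baseline.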

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

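The 3 tests of why the FRISf2-flc3 day 2 array stands apart were chosen after its values were seen. Of 30 sets of 4 arrays of 1 day compared on 10 measures, 7 had an array far from the others, where chance gives about 1 in 20. On the FRISf2-flc3 day 2 array these were the hybridisation controls BioB at 9.53 and BioC at 9.90 (log2), the 3' minus 5' difference of GAPDH at 1.36, the interquartile range at 3.33 and the 5th percentile at 2.82. On the FRISf2-FLC day 0 array BioB was 7.30 and the residual spread 0.0969, both the lowest of the 4 day 0 arrays.

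Of the 4 hybridisation controls, 4 lay above the range of the other 11 arrays on FRISf2-flc3 day 2 by more than that range, with BioB at 9.53 against 7.14 to 7.79. This is consistent with less labelled sample RNA on that array, though more of the control mix would look alike. A sample of another genotype is argued against: 17501_s_at differed by 0.0343 from the other FRISf2-flc3 arrays and by 3.37 from the FRISf2-FLC mean, and AT4G01590 by -0.43 from the former and by 2.34 from the nearest Col-allele genotype. Both probe sets were picked from fits that include this array under its label, so the check is not independent of that label. Degraded RNA stays open, since 1 of GAPDH and ubiquitin had a 3' minus 5' difference above the other arrays (GAPDH 1.36 against 0.765 to 1.16). No biological explanation was tested.

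Differences between genotypes in the same effect drew attention to 3 probe sets. The FLC effect was larger with active FRI by 2.23 for 17501_s_at and by 0.98 for 16586_s_at, and the day 4 response of 12876_at was lower in FRISf2-FLC, with a difference of -3.05 from values that lay partly under the filter value of 3.56, each by limma's test of the difference itself.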

How the results depend on the processing

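Array weights were added after the data were seen. Of 83 values of named probe sets, 56 stayed past the threshold under every setting run and 27 did not under at least 1. Most of the 56 were day 2 or day 4 values, of which only a THI2.1 value on day 2 was lost (kept in 19 of 20 settings). In the other comparisons, AT4G01590 was the only gene with a name that kept every call, for the FRI effects with and without FLC. The number of settings differed between probe sets, with 20 for AT4G01590 and 21 for AT1G52100 in the FRI effect with FLC. Over all 1662 pairs of value and setting, 1508 stayed, 154 did not and 0 changed sign. For FRISf2-FLC against the other genotypes (47 calls), quantile normalization gave 30, day as a number 9 and array weights 155; leaving out 1 array gave 5 to 44, with 5 without FRISf2-FLC day 2, 20 without FRISf2-FLC day 4, 21 without friCol-FLC day 4, 22 without FRISf2-flc3 day 4, 27 without FRISf2-flc3 day 0, 30 without friCol-FLC day 0 and 31 without friCol-flc3 day 4. For the FLC effect with active FRI (9), the 50th percentile filter gave 15, a robust trend 14, the 6 arrays alone 30 and array weights 96; leaving out 1 array gave 2 (FRISf2-flc3 day 0) to 27 (FRISf2-FLC day 0), with 3 without FRISf2-flc3 day 4, 4 without each of friCol-FLC day 4, FRISf2-FLC day 2 and FRISf2-flc3 day 2, 19 without friCol-FLC day 2 and 24 without friCol-flc3 day 4. For the FLC effect without active FRI (1), day as a number and the 6 arrays alone each gave 0; leaving out 1 array gave 0 to 2, with 2 without friCol-FLC day 4 (CCL not among them) or FRISf2-FLC day 2 and 0 without any of friCol-FLC day 0 and day 2, friCol-flc3 day 0, day 2 and day 4, FRISf2-FLC day 0 and FRISf2-flc3 day 0.

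For the FRI effect with FLC (11), day as a number gave 5 and array weights 44; leaving out 1 array gave 6 (friCol-FLC day 0 or day 2) to 18 (FRISf2-FLC day 0), with 7 without FRISf2-FLC day 2. For the FRI effect without FLC (5), the 50th percentile filter gave 2, day as a number 3, the 6 arrays alone 11 and array weights 18; leaving out 1 array gave 5 to 7. For the interaction (2), array weights gave 9, and day as a number gave 2, of which 1 was among the main calls. Leaving out 1 array gave 0 (friCol-flc3 day 0 or day 4, FRISf2-FLC day 2, FRISf2-flc3 day 0 or day 4) to 9 (FRISf2-FLC day 0). The count was then 1 without friCol-FLC day 0 or friCol-flc3 day 2, and 4 without friCol-FLC day 2 or day 4. For day 2 (661), leaving out 1 array gave 422 to 709, with 422, 428 and 432 without the day 0 arrays of friCol-flc3, friCol-FLC and FRISf2-flc3. For the day 4 response of FRISf2-FLC (1), the 50th percentile filter gave 0, no trend 2, a robust trend 2 and array weights 16; leaving out 1 array gave 0 (friCol-flc3 day 4) to 1. The day 4 count (1130) was 791 to 1454 when 1 array was left out, and 769 to 1563 over all settings. Without FRISf2-flc3 day 2 it was 1454, with 1126 of the 1130 shared, and the day 2 count was 709, with 549 of the 661 shared. A segment ending at AT4G00999 gave an exact p of 1 for the FRI effect without FLC, as AT4G01590 then lies outside. Leaving out an array or fitting 6 arrays lowers the residual degrees of freedom; otherwise the cause was not tested. Without FRISf2-FLC day 0 or day 4 the day 4 response of FRISf2-FLC could not be fitted, and the pseudocount alternatives were not run because the values are logarithms. No detection calls were used here, so limits from signal over background were not assessed.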

Other observations

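The tests of the response size, of the locus bins, of the splits for FRISf2-FLC and the interaction, and of the splits balanced over days or genotypes were chosen after the results were seen; the other splits were fixed before. Of the 27 probe sets higher in FRISf2-FLC, 23 were called down on day 4, and of the 20 lower in FRISf2-FLC, 15 were called up and 1 down. The genotype difference is a mean over the 3 days, so this pairing is not independent of a smaller day response in FRISf2-FLC. Of the 38 probe sets higher and called down or lower and called up, 31 differed more on day 4 than on day 0 and 7 did not, with medians of the absolute difference of 0.38 on day 0 and 0.70 on day 4 (log2). For AT1G76960 the difference was 0.38 on day 0 and 1.80 on day 4, for BGLU47 0.53 and 0.40, and for AT2G31790 0.35 and 0.26.

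FRISf2-flc3 lay apart from the means of every other genotype on a pair of probe sets. Its difference from friCol-FLC was not tested, and of this pair only 16586_s_at passed for the interaction. 16341_at measured 5.60 ± 0.399 (SD over 3 days, log2) there and 4.26, 4.31 and 4.29 as the means of friCol-FLC, friCol-flc3 and FRISf2-FLC, and 16586_s_at measured 4.55 ± 0.144 against 5.68, 5.67 and 5.55.

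The day response measured smaller in FRISf2-FLC, with a day 4 ratio to the other genotypes of 0.80, part of which the choice of probe sets may cause. A candidate explanation, as a hypothesis, is the presence of active FRI together with FLC in that genotype. Compressed values on its arrays are argued against, since the interquartile range on day 4 was 3.59 there and 3.53 to 3.58 in the other genotypes. A day 0 array that already looked induced is argued against too. The excess at day 0 was 0.0192 on the day 2 probe sets and -0.0323 on the day 4 probe sets, against shortfalls of 0.265 and 0.158. The choice of probe sets may enlarge these shortfalls, but the day 4 excess was negative. The genotype was lowest of 4 on both days, but chance puts a given genotype lowest in 1 of 4 cases on a day, so the genotype and a difference between lots of plants cannot be told apart. Without the FRISf2-flc3 day 2 array the ratios were 0.594 and 0.775.

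In the FRI effect without FLC, probe sets with an unadjusted p under 0.05 made up a larger share near FRI than elsewhere. Most of them lay elsewhere, with 17 in the segment and 179 outside. Of the 5 probe sets called after adjustment only AT4G01590 had a locus name, so the place of the others is not known. Of 39 bins of 3000 locus numbers with at least 20 probe sets, the one holding the segment ranked 1 for the share with an unadjusted p under 0.05 in the FRI effect without FLC (17 of 81, 21.0%, against 6.75% elsewhere), and the fold changes of its probe sets correlated between the FRI effects with and without FLC (r = 0.784 across probe sets, 0.590 without AT4G01590, 0.0136 elsewhere; probe sets are not independent replicates). The share and the correlation fit genes of the introgressed Sf-2 segment as a source. Another bin, the one from AT2G15000, reached r = 0.563, close to the 0.590 of the segment without AT4G01590. Bins with fewer than 20 probe sets were left out, so the scan does not cover the genome evenly. Of the 17, 12 had the same sign with FLC and 5 did not, and 4 of 81 were under 0.05 in both FRI effects with the same sign, against 10 of 2653 elsewhere; among the 12, AT4G00780, AT4G02360 and 1 of 2 probe sets of AT4G01395 (0.95 and 0.86, -1.0 and -0.78, -0.39 and -0.37 without and with FLC) did not pass after adjustment. Whether probe mismatches to Sf-2 sequence alone account for the larger share near FRI stays open: 23.5% of the 17 were higher with the Sf-2 allele, and no Sf-2 sequence was used here.

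Other splits of the arrays were fitted with the same models. For day 4, 1 of 35 splits into 4 and 4 gave as many calls, the real one (1130, highest other 1). For day 2 it was also 1 of 35 (661, highest other 1), each a share under 0.05 over these splits. They ignore genotype and leave the day difference in the residual spread; the splits that keep both days in each genotype number 8, too few for a share under 0.05 (highest other 0 for day 4 and 1 for day 2). For FRISf2-FLC against the others, 1 of 100 drawn splits into sets of 3 gave as many, the real one (47, highest other 7), a share under 0.05. These splits ignore day, and splits of single arrays cannot tell genotype from a difference between lots of plants. Over 100 drawn splits with 1 array of each day in each set, the real one was again the only one to reach 47, with the highest other at 33 and the next at 3, and the real count itself was 5 without FRISf2-FLC day 2. For the interaction, 11 of 100 gave 2 or more calls (highest other 9), so chance cannot be excluded over these splits, while of 100 splits balanced over days 4 gave 2 or more (highest other 4), a share under 0.05. The answer for that count therefore rests on which splits are used, and it stays open. The splits for these 2 comparisons were first counted in a model with 2 sets of arrays and day alone, where the real counts were 40 and 0, and then changed to the model of the report. For the effect of FLC with and without active FRI and of FRI with and without FLC, 3 against 3 arrays make 10 splits, too few for a share under 0.05; the real counts were 9, 1, 11 and 5, each reached by 1 split, and the highest other was 0 in each.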
